A study of Mus musculus with 4 samples.

How the data were processed

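RNA sequencing was done on 4 samples of YAMC cells, colonocytes per the labels, 1 per group: control siRNA in medium, control siRNA with TNF, Sirt6 siRNA in medium and Sirt6 siRNA with TNF. Per the labels' protocols, cells of passages 10 to 12 received 50 nM siRNA, and 48 h after transfection they were given TNF at 100 ng/mL or medium alone for 24 h. The maintenance medium at 33 °C contained interferon-γ, which was left out from 24 h after transfection, when the cells were moved to 37 °C. The siRNA sequences were not given in the sources used here. Total RNA was extracted, polyadenylated RNA was selected on oligo-dT beads and libraries were made with a NEBNext Ultra kit, per the labels' protocols.

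The deposited table holds 29179 genes with Ensembl mouse gene identifiers. It gives read counts per gene for each of the 4 samples, per the file headers, and the values are whole numbers. It also gives deposited values headed RPKM, but each equals the read count divided by the library total, scaled so that each library sums to 1000000, to within 0.0005, with no gene length, so they are RPM (counts scaled to library size alone). CASAVA, Bowtie 1.0.1 and edgeR were named for the processing, per the submitters' processing notes, without their steps. The genome build, the annotation and the read counter were not given in the sources used here, so no positions are given. Gene names are those of the table. Of its identifiers 27928 were matched in a reference table of names, and 27 names that a spreadsheet had turned into dates were restored through their identifiers.

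Totals were 22422365, 18793708, 23749380 and 21755516 reads in the order of the groups above. A count of 0 allows up to 3 reads, or 0.134, 0.160, 0.126 and 0.138 RPM. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Some genes had identical reads in all 4 libraries. Sequence shared between genes was measured as the percent of a gene's 50-base sequences that also occur, on either strand, in transcripts of another gene. Overlap of genes on opposite strands is therefore included. Of 89 named genes, 11 shared over 10% and 3 over 50%.

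Counts were analysed with Python 3.11.15 and with edgeR 4.0.16 in R 4.3.3. Genes with at least 1 RPM in at least 1 library were kept, which left 15274; 7837 genes had no read. Library sizes were scaled by TMM over all 4 libraries, log2 ratios were computed with a prior count of 2, and levels are given as TMM-normalised RPM. A gene passed the size rule at a ratio of at least 2 either way with an exact conditional binomial 95% interval of the read ratio, computed without the prior count, that left out 1. Levels of Sirt6 and Rspo1 have exact Poisson intervals. The difference of the TNF responses is the log2 ratio with Sirt6 siRNA minus that with control siRNA. It passed at a size of at least 1 with a delta-method 95% interval, with 0.5 added to each count, that left out 0. No p-value was computed for a comparison of 2 libraries, since neither group has a replicate. An edgeR quasi-likelihood test of an additive model (siRNA and TNF, 1 residual degree of freedom) was run as an alternative, and its p-values rest on a spread pooled over all genes (common biological coefficient of variation 0.039), drawn from how far the responses differed, not on each gene's own difference or on replicates. Where a gene had no read in the denominator, the fold is a lower bound against the floor of 3 reads per library.

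The samples, comparisons, 25 gene lists, alternatives and naming rule were fixed before the data were examined. A list was described by the median log2 ratio of its measured members and by that median's percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. It was said to lie apart in the lowest or highest 2.5%, which describes these libraries and is not a p-value. Each list was examined in 5 ways (4 comparisons and the difference), or 125 in all. The lists held 713 entries, of which 2 were not matched by that name in the table. One chemokine, Cxcl3, had no read in 1 library, and putting it at its bound left the list's median at 1.328 for TNF and at -0.087 for silencing.

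Genes were named by rule. Sirt6, the other sirtuins and Rspo1 were always named. For TNF and for silencing, up to 10 genes higher and 10 lower were named among those past the size rule the same way in both comparisons, taking those whose counting interval stayed farthest from no change in the weaker comparison. These are the genes called firmest. For the difference, 6 were named each way in the same manner, and in each list up to 4 members past the size rule with the largest mean ratio. Unnamed gene models and small RNAs were left out. The values of 2 genes that the rule would name are not reported here. Genes chosen after their values were seen are identified as such.

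The procedures were tested on simulated counts for the 15274 genes, with 200 genes changed. The minimum of 1 RPM was not applied again to the simulated counts, so false calls among thinly read genes may be understated. With counting error alone, the size rule for TNF with control siRNA recovered 48.5% of genes changed 2-fold, 99.5% at 3-fold and 100% at 4-fold, with 21 to 25 false calls. Requiring both TNF comparisons recovered 25.5% at 2-fold and 98.5% at 3-fold with 0 false calls. With no true change, and with or without a fitted spread added, 15 to 25 genes passed for silencing in medium and 0 to 1 in both silencing comparisons. For the difference 69 to 104 passed. The additive model for TNF recovered 100% at 3-fold with 8 false calls. Of 200 random lists of 25 genes, 5.0% lay apart with counting error alone and 7.0% with added spread.

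Alternatives were DESeq2 1.42.0 size factors, upper-quartile and total-count scaling, no filter, a minimum of 5 RPM, and fold thresholds of 1.5 and 3. Others were a prior count of 5, the deposited RPM with a pseudocount of 1, random lists without matching, list means and the additive model. With the deposited RPM the counting interval was not required.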

Results

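Messenger RNA was sequenced from 4 cultures of YAMC cells, a conditionally immortalised line that the labels describe as young adult mouse colonocytes. The cells had received either a control siRNA or an siRNA against Sirt6, a nuclear NAD-dependent deacylase, and were then kept in medium or given the inflammatory cytokine tumour necrosis factor (TNF). Each of the 4 combinations was 1 library, with 22422365 gene-assigned reads for control siRNA in medium, 18793708 for control siRNA with TNF, 23749380 for Sirt6 siRNA in medium and 21755516 for Sirt6 siRNA with TNF. A group of 1 library has no replicate error, so every difference given here compares libraries, not conditions, and has no replicate check. Intervals are 95% intervals of counting error only, and "rose" and "fell" are used only for genes with a ratio of at least 2 whose interval leaves out 1. Of 29179 genes in the table, 15274 had enough reads to be compared.

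Sirt6 (ENSMUSG00000034748) was lower in both libraries labelled Sirt6 siRNA. Its level was 17.13 normalised RPM (15.47 to 18.92) with control siRNA in medium and 18.80 (16.89 to 20.87) with control siRNA and TNF. With Sirt6 siRNA it was 7.11 (6.08 to 8.26) in medium and 7.03 (5.95 to 8.25) with TNF. The ratio to control, computed with the prior count of 2 reads, was 41.8% (34.5 to 49.8) in medium and 37.7% (30.7 to 45.4) with TNF. None of the other 6 sirtuins passed the size rule in any of the 4 comparisons. The log2 ratio for Sirt6 siRNA was -0.27 in medium and -0.05 with TNF for Sirt1, and -0.00 and -0.07 for Sirt7. The sirtuin list, 7 genes with Sirt6 among them, did not stand apart from random lists of like expression, with a median log2 ratio of 0.217 in medium and -0.073 with TNF for Sirt6 siRNA, and of 0.133 and -0.103 for TNF.

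**Figure D1:**
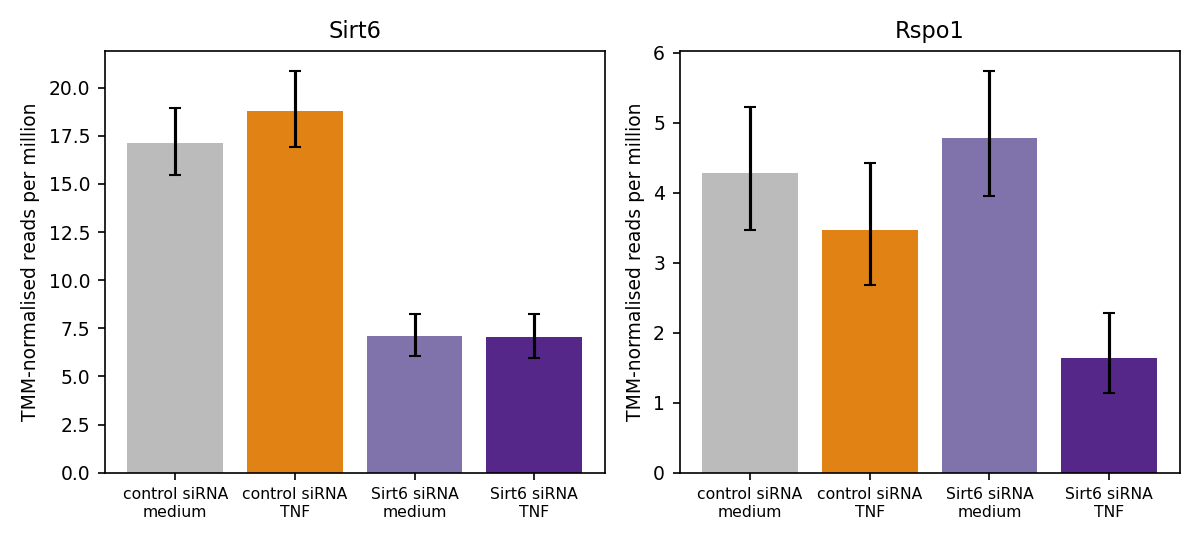
Levels of Sirt6 (left) and Rspo1 (right) in each of the 4 libraries, in TMM-normalised RPM. Bars are single libraries and lines are 95% Poisson intervals of the read count; Sirt6 lies at 17.13 and 18.80 with control siRNA and at 7.11 and 7.03 with Sirt6 siRNA, and Rspo1 is lowest, at 1.64, with Sirt6 siRNA and TNF.

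The study sought genes that depend on Sirt6 under inflammatory stimulation. The first comparison asked what TNF changed in cells with control siRNA and in cells with Sirt6 siRNA. Genes of acute inflammation were among those that rose most firmly. Csf2, which encodes the growth factor GM-CSF, was 33.5-fold higher with TNF in the control siRNA libraries (log2 5.07, interval 4.45 to 6.33) and 38.2-fold higher in the Sirt6 siRNA libraries (log2 5.26, 4.53 to 7.41). The neutrophil chemokine Cxcl2 was 22.5-fold and 19.4-fold higher, the nitric oxide synthase Nos2 16.7-fold and 34.5-fold, and Ccl20, a chemokine for cells that carry the receptor Ccr6, 12.7-fold and 21.5-fold. Of 33 genes of cholesterol and fatty acid synthesis, 8 fell with control siRNA and 9 with Sirt6 siRNA, among them Hmgcs1, an early enzyme of cholesterol synthesis, which was 3.22-fold and 4.18-fold lower (log2 -1.69, -1.82 to -1.56, and -2.06, -2.18 to -1.96). In all, 539 genes passed the size rule with control siRNA (350 higher, 189 lower) and 559 with Sirt6 siRNA (332 higher, 227 lower). At a 1.5-fold threshold the balance with Sirt6 siRNA turned, with 676 higher and 818 lower. The same direction was found in both for 328 genes, 248 higher and 80 lower, where independent lists of these sizes would share 7.61 and 2.81. The expected numbers take every gene as equally likely to pass, and are too low where calls gather among thinly read genes. The pairs of libraries behind the 2 counts have no library in common.

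Among the other genes that rose most firmly under both siRNAs were Saa3, an acute phase serum amyloid gene (11.4-fold and 14.8-fold), Ch25h, which makes 25-hydroxycholesterol (10.8-fold and 11.5-fold), and Pglyrp3, a peptidoglycan recognition protein gene (14.6-fold and 12.5-fold). Rgs16, a regulator of G protein signalling, was 14.8-fold and 14.7-fold higher. Sprr2e, a cornified envelope gene, and Mmp9, a matrix metalloprotease gene, had 2 reads each in both medium libraries. Their log2 ratios were 4.52 (3.62 to 8.59) and 4.75 (3.91 to 8.87) for Sprr2e, and 4.24 (3.32 to 8.31) and 4.62 (3.77 to 8.73) for Mmp9. Among those that fell most firmly were Igfbp5, which encodes an insulin-like growth factor binding protein (9.53-fold and 6.38-fold lower), Spon2 (5.28-fold and 4.69-fold), Zc2hc1c (5.03-fold and 4.35-fold) and the retinaldehyde reductase gene Dhrs3 (4.14-fold and 4.41-fold). Esyt3 was 3.18-fold and 3.86-fold lower, and Cdon, a co-receptor for hedgehog ligands, 2.59-fold and 2.98-fold.

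**Figure D2:**
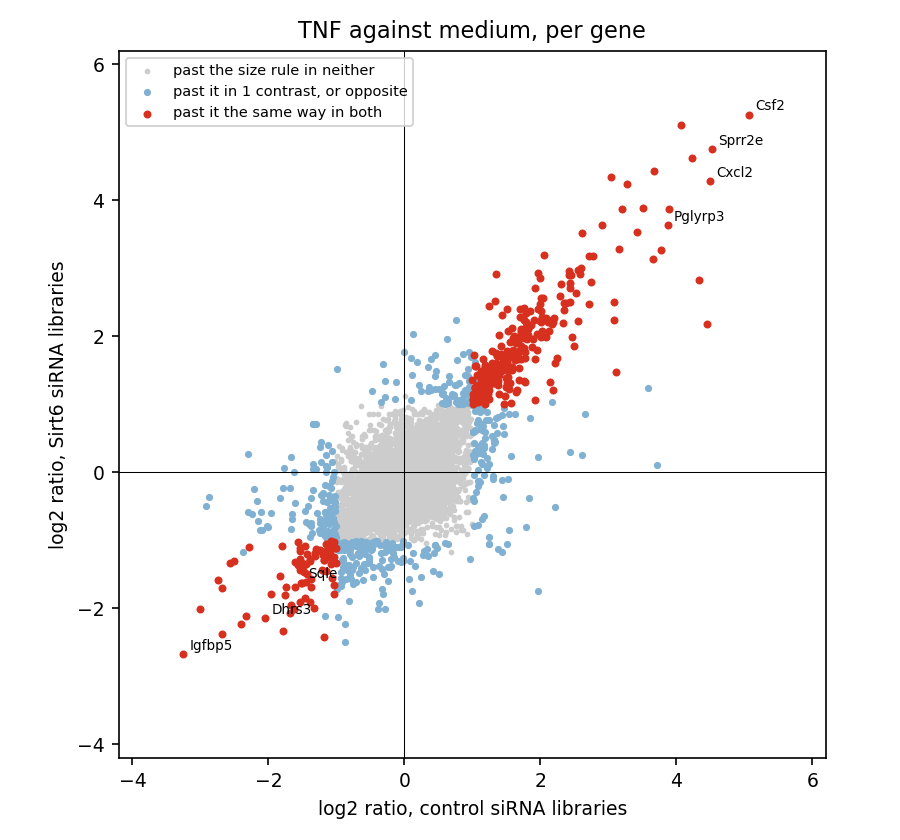
Log2 ratio of TNF to medium for each of 15274 genes, in the control siRNA libraries (horizontal) and in the Sirt6 siRNA libraries (vertical). Red points are the 328 genes past the size rule the same way in both, and labels name some of the genes of the fixed naming rule.

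By list, 8 of 25 gene lists lay above random lists of like expression in both TNF comparisons and 7 lay below. Of 37 measured NF-kB targets and regulators, 25 rose with control siRNA and 26 with Sirt6 siRNA, and none fell (median log2 1.389 and 1.396), with Mmp10, a stromelysin gene, 12.5-fold and 8.79-fold higher. Of 20 measured chemokines, 12 rose in each comparison (median 1.328 and 1.343). Cxcl1 was 6.12-fold and 11.4-fold higher, while Cxcl3 had no read with control siRNA in medium and was at least 14.5-fold higher with TNF there, against a floor of 3 reads, and 4.52-fold higher with Sirt6 siRNA. Of 40 interferon-stimulated genes, 30 and 34 rose and none fell (median 1.363 and 1.636). Among them were the guanylate-binding protein genes Gbp2 (5.46-fold and 7.47-fold) and Gbp5 (6.58-fold and 5.56-fold), Ifit3 (5.33-fold and 7.5-fold) and Parp14 (5.09-fold and 5.63-fold). Ifit3 shares 51.2% of its 50-base sequences with Ifit3b, so its reads cannot be assigned to 1 gene. Of 13 measured acute phase and complement genes, 4 and 5 rose (median 0.557 and 0.549), among them Lcn2, an iron-siderophore binding protein gene (3.88-fold and 3.47-fold), the pentraxin gene Ptx3 (2.76-fold and 3.03-fold), and complement factor B, Cfb (4.03-fold and 5.89-fold), which shares 73.0% of its sequence with the overlapping model Gm20547. Of 20 genes of MHC class I antigen presentation, 3 rose in each comparison (median 0.454 and 0.405): the immunoproteasome gene Psmb10 (2.87-fold and 2.80-fold), the peptide transporter gene Tap2 (2.01-fold and 2.08-fold) and Tapbpl (2.03-fold and 2.20-fold).

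Smaller shifts upward were found for 3 more lists. The 20 measured immediate early genes had medians of 0.255 and 0.238, and 1 rose, Fosl1, an AP-1 transcription factor gene (2.38-fold and 2.67-fold), which shares 52.6% of its sequence with Ccdc85b. The 25 p53 targets had medians of 0.189 and 0.181, and 1 rose, the death receptor gene Fas (2.05-fold and 2.39-fold), which is also in the apoptosis list. Of 35 measured apoptosis regulators (median 0.079 and 0.111), 3 and 4 rose, among them Birc3, an inhibitor of apoptosis and NF-kB target (3.27-fold and 4.15-fold), the inflammatory caspase gene Casp4 (2.20-fold and 2.68-fold) and, in the Sirt6 siRNA libraries, Bid (2.11-fold).

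Of the lists that lay lower, cholesterol and fatty acid synthesis moved most. Its medians were -0.740 and -0.759 and none of its genes rose, with the sterol sensor gene Insig1 3.07-fold and 4.03-fold lower and the squalene epoxidase gene Sqle 2.84-fold and 3.08-fold lower. The 36 measured Wnt and R-spondin pathway genes had medians of -0.199 and -0.251. With control siRNA 2 of them fell and 1 rose, and with Sirt6 siRNA 3 fell and 4 rose. Lgr4, a receptor for R-spondins, was 2.06-fold and 2.14-fold lower, and the ligand gene Wnt10a was 2.34-fold and 2.22-fold higher. The ligand gene Wnt2b was 2.57-fold and 1.85-fold lower, past the rule with control siRNA alone, and Rspo3 was 1.8-fold and 2.0-fold higher, past it with Sirt6 siRNA alone. Their differences (log2 0.47 and 0.16) did not pass. Medians were -0.10 and -0.092 for 36 proliferation genes and -0.102 and -0.085 for 22 NRF2 antioxidant genes, with no member past the size rule. For 40 measured extracellular matrix genes they were -0.081 and -0.119, with Col6a3, at 16 and 3 reads, past the rule with control siRNA (log2 -1.66, -4.56 to -0.34). The 20 measured fibroblast markers had medians of -0.153 and -0.132, and 1 fell, Des, with Sirt6 siRNA (2.69-fold). They did not lie apart by their mean (percentiles 15.54 and 7.69) or with a minimum of 5 RPM (6.4 and 3.91). Only 9 of 30 epithelial markers had enough reads (median -0.345 and -0.247), and 1 rose, the transcription factor gene Ehf, with control siRNA (2.53-fold). By their mean these did not lie apart (percentiles 21.8 and 17.74), nor with Sirt6 siRNA without a filter (47.84). The junction list (14 of 24 measured) lay lower with control siRNA alone (median -0.137 and -0.034), with Cldn15 2.04-fold lower in both comparisons. Ocln, from 32 reads to 2, was 7.56-fold lower with control siRNA and did not pass with Sirt6 siRNA. Immune cell markers, 4 of 22 measured, and endothelial markers, 7 of 12 measured, lay higher with Sirt6 siRNA alone (medians -0.031 and 0.566, and 0.135 and 0.253); 1 immune marker, the endotoxin co-receptor gene Cd14, was 2.11-fold and 2.12-fold higher. The difference between the 2 TNF responses did not lie apart for the junction, immune or endothelial list, and is given for each list further on.

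For TNF, 6 lists besides the sirtuins stayed within the range of random lists in both comparisons. Their medians were 0.104 and 0.037 for hypoxia response, where 1 gene, Car9, fell with Sirt6 siRNA (2.33-fold), 0.054 and 0.104 for cytosolic ribosomal proteins, and 0.040 and 0.040 for the unfolded protein response. They were -0.012 and -0.041 for DNA double-strand break repair, -0.018 and -0.021 for glycolysis and glucose uptake, and -0.071 and -0.015 for nuclear genes of oxidative phosphorylation. An additive edgeR model of all 4 libraries, which has 1 residual degree of freedom and 1 spread pooled over genes, gave 2206 genes higher and 2300 lower with TNF at an adjusted p of at most 0.05. The genes found under both siRNAs had a median of 323.6 reads per library, against 71.8 for the 539 and 100.8 for the 559, of which 43.6% and 37.4% had under 50 reads. With a minimum of 5 RPM those counts were 284 and 321. With random lists not matched on expression, 9 of the 15 lists lay apart both times, which left out the proliferation, NRF2, extracellular matrix, epithelial, fibroblast and apoptosis lists.

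**Figure D3:**
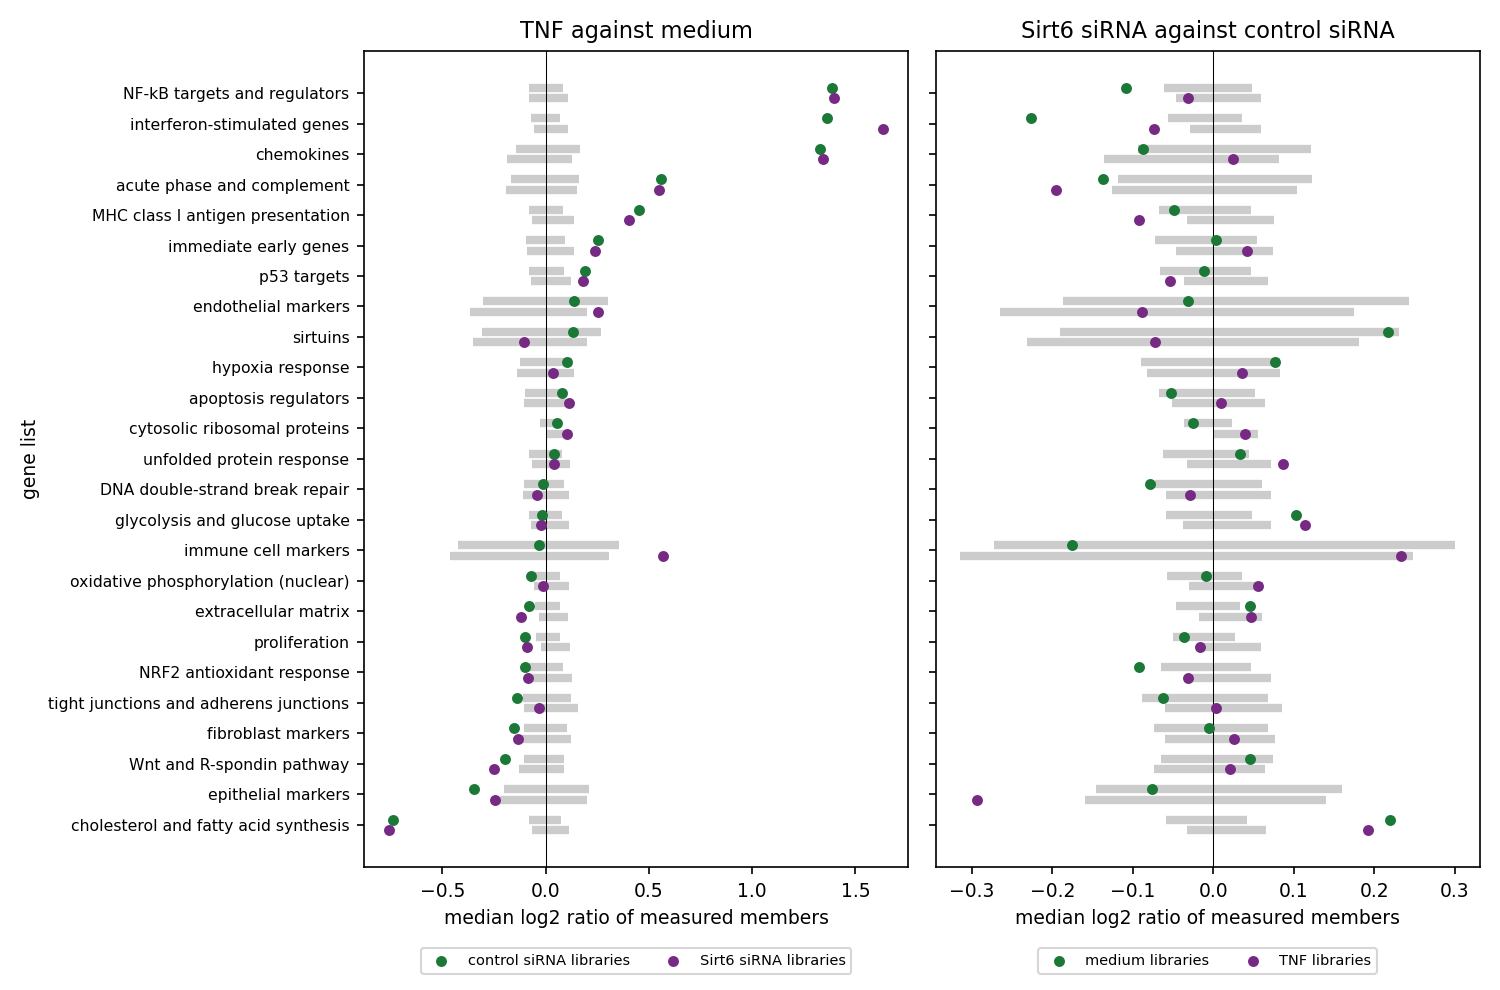
Median log2 ratio of the measured members of 25 gene lists for TNF against medium (left) and Sirt6 siRNA against control siRNA (right). Each dot is 1 pair of libraries, and grey bars span the middle 95% of 10000 random lists of the same size and like expression; cholesterol and fatty acid synthesis lies at -0.740 and -0.759 on the left and at 0.219 and 0.192 on the right.

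The second comparison asked what the Sirt6 siRNA changed in medium and with TNF. Besides Sirt6 itself, the most deeply read gene that fell in both was Cx3cl1, the membrane-bound chemokine fractalkine. It was 3.11-fold lower with Sirt6 siRNA in medium (log2 -1.63, -2.00 to -1.32) and 2.29-fold lower with TNF (log2 -1.20, -1.36 to -1.04), at 12.8 and 4.07 RPM in medium and 50.6 and 22.0 with TNF. Gdf15, a stress-induced cytokine of the TGF-beta family, was 2.89-fold and 2.47-fold lower. Stmn4, a neuronal stathmin that binds tubulin, was 4.16-fold and 2.80-fold higher (log2 2.06, 1.59 to 2.68, and 1.48, 1.09 to 1.95), and Fam131b was 2.48-fold and 2.08-fold higher. The size rule was passed by 155 genes in medium (75 higher, 80 lower) and by 160 with TNF (60 higher, 100 lower). Of these, 8 were higher in both and 18 lower in both, Sirt6 among them, where independent lists would share 0.29 and 0.52. These expected numbers take every gene as equally likely to pass, and are too low because the calls gathered among thinly read genes.

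The other named genes that rose in both were read thinly, with 4 to 61 reads in each library. They included Baiap2l2, whose product shapes membranes (2.62-fold and 4.56-fold), Ccr7, a chemokine receptor gene (3.75-fold and 2.15-fold), Lrrc73 (2.16-fold and 2.79-fold), the neuronal growth cone gene Gap43 (2.25-fold and 2.08-fold) and Rassf4 (2.51-fold and 2.16-fold). The other named genes that fell in both had 5 to 53 reads. They included Heph, a copper-dependent ferroxidase of intestinal iron export (3.08-fold and 2.95-fold), the galectin gene Lgals7 (3.11-fold and 3.55-fold), the mucin-type glycosyltransferase gene Gcnt3 (3.13-fold and 2.83-fold), Efs (2.60-fold and 2.94-fold), Kcnab3 (2.32-fold and 4.26-fold), Zfp385b (5.46-fold and 2.51-fold) and the matricellular gene Postn (2.5-fold and 3.39-fold).

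**Figure D4:**
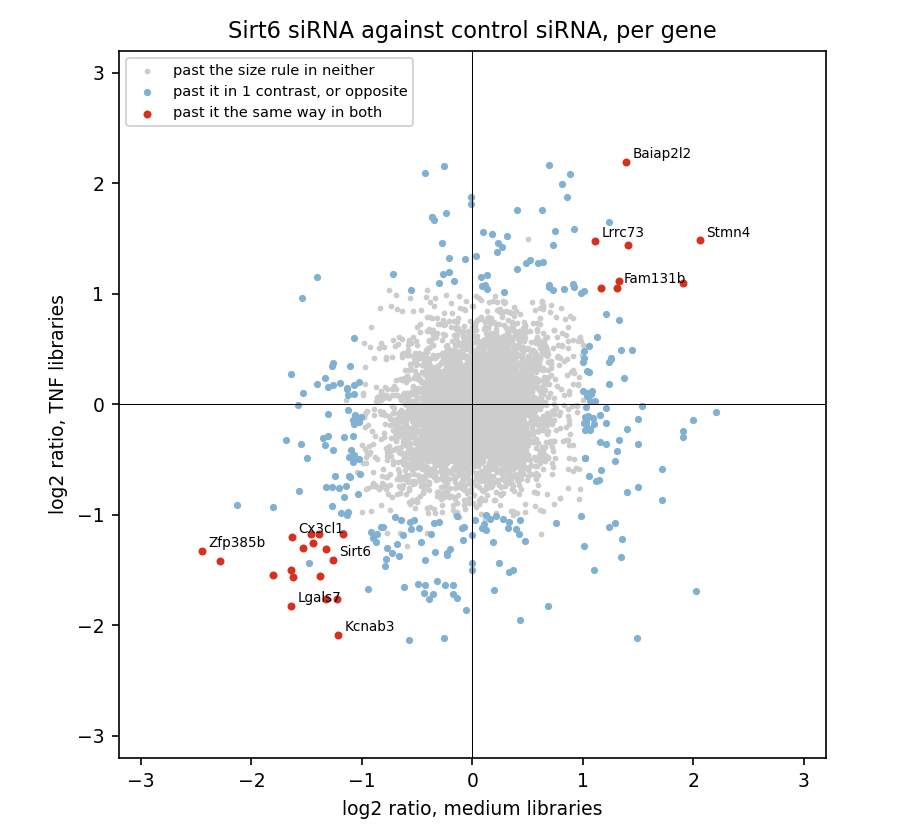
Log2 ratio of Sirt6 siRNA to control siRNA for each of 15274 genes, in medium (horizontal) and with TNF (vertical). Red points are the 26 genes past the size rule the same way in both, and labels name some of the genes of the fixed naming rule.

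For silencing, 2 lists lay above random lists of like expression in both comparisons and 2 lay below. All 4 shifts were small. The 33 genes of cholesterol and fatty acid synthesis had medians of 0.219 in medium and 0.192 with TNF. The 26 genes of glycolysis and glucose uptake had medians of 0.102 and 0.114, with no member past the rule. The 40 interferon-stimulated genes had medians of -0.227 and -0.074, with no member past the rule. The 13 measured acute phase and complement genes had medians of -0.137 and -0.196, with Serping1, the C1 inhibitor gene, 2.40-fold lower in medium, from 21 and 8 reads. Of the 13, 5 had a ratio above 0 in medium and 4 with TNF, among them the more deeply read Ptx3 (log2 0.45 and 0.59). With a minimum of 5 RPM this last list did not lie apart in medium (percentile 21), and without a filter it did so in neither comparison (57.12 and 7.23).

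Of the remaining lists, 3 lay apart on the lower side in medium and stayed within the random range with TNF. They were NF-kB targets and regulators (median -0.108 in medium and -0.032 with TNF), NRF2 antioxidant genes (-0.092 and -0.032) and DNA double-strand break repair (-0.079 and -0.029). Of the NF-kB genes, Nos2 was 2.54-fold lower in medium, from 20 and 7 reads. Ratios in medium also rose with GC content across genes (Spearman correlation 0.264), on which the random lists were not matched. The extracellular matrix list lay higher in medium and within the random range with TNF, though its medians were alike (0.046 and 0.047). In it Postn fell in both comparisons and Col6a3, from 3 reads to 14, rose with TNF (log2 1.57, 0.19 to 4.47). Within the random range in medium but lower with TNF were MHC class I antigen presentation (-0.049 and -0.092) and p53 targets (-0.012 and -0.054). So were epithelial markers (-0.076 and -0.294), while the unfolded protein response lay higher with TNF (0.033 and 0.087). Of the p53 targets, Gdf15 fell in both comparisons. The silencing ratio with TNF minus that in medium is also the difference of the TNF responses, given further on. It lay apart for none of the lists named so far in this paragraph. None of these shifts is therefore shown to differ between medium and TNF. The other lists stayed within the random range. Their medians in medium and with TNF were -0.087 and 0.024 for chemokines, where Ccl17 was 2.57-fold lower with TNF and Cxcl3, unread with control siRNA in medium, was at least 2.51-fold higher there. They were 0.045 and 0.021 for the Wnt and R-spondin pathway. There Sox9, a target of Wnt signalling, was 2.19-fold lower in medium, from 54 and 25 reads, but not with TNF (log2 -0.05). Rspo1 was 2.06-fold lower with TNF, and Wnt10a was 1.79-fold and 1.71-fold higher, short of the rule. Medians were 0.076 and 0.035 for hypoxia response, where Ankrd37 was 2.09-fold higher in medium. For junctions they were -0.063 and 0.003, where Ocln, at 2 and 17 reads, was 4.47-fold higher with TNF. They were -0.025 and 0.039 for cytosolic ribosomal proteins, -0.036 and -0.016 for proliferation, -0.005 and 0.026 for fibroblast markers, -0.176 and 0.233 for immune cell markers, -0.031 and -0.089 for endothelial markers, -0.009 and 0.055 for oxidative phosphorylation, 0.003 and 0.042 for immediate early genes and -0.052 and 0.009 for apoptosis regulators.

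The counts for silencing rest on thinly read genes: 86.5% of the genes called in medium and 86.2% of those called with TNF had under 50 reads per library on average, and with a minimum of 5 RPM in any library the counts were 14 and 15, with 4 in both. With TNF the balance then turned, to 9 higher and 6 lower. The additive edgeR model gave 524 genes higher and 482 lower with Sirt6 siRNA at an adjusted p of at most 0.05, with adjusted p of 1.76e-20 for Sirt6, 5.35e-32 for Cx3cl1, 2.38e-14 for Stmn4 and 4.34e-06 for Gdf15, each in the direction given above in both comparisons. These p-values rest on a spread pooled over genes, not on replicates or on each gene's own spread. Matches of the siRNA to other transcripts, such as Cx3cl1, were not checked, so off-target changes are not told apart from changes through Sirt6.

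The third comparison asked whether the TNF response differed between Sirt6 siRNA and control siRNA. Rspo1 (ENSMUSG00000028871), a secreted agonist of Wnt signalling, was named beforehand because the study is known to concern it. Its level was 4.28 RPM (3.47 to 5.22) with control siRNA in medium, 3.47 (2.68 to 4.42) with control siRNA and TNF, 4.78 (3.95 to 5.74) with Sirt6 siRNA in medium and 1.64 (1.14 to 2.28) with Sirt6 siRNA and TNF, from 97, 65, 115 and 35 reads. With TNF it was 2.81-fold lower in the Sirt6 siRNA libraries (log2 -1.49, -2.13 to -0.99), while the ratio in the control siRNA libraries did not pass the rule (log2 -0.30, -0.78 to 0.17). The difference of the 2 responses was -1.20 in log2 (-1.94 to -0.52) and passed the rule. Because the study may have chosen Rspo1 from these libraries, they are not independent evidence for its direction.

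Across all genes the difference passed the rule for 256, 91 with a higher TNF ratio under Sirt6 siRNA and 165 with a lower one. The 6 firmest on the higher side were Prss16, a thymus-specific serine protease gene (log2 difference 2.5, 1.23 to 4.29), Slc17a9, a vesicular nucleotide transporter gene (2.52, 1.12 to 4.64), Rnf135, a ubiquitin ligase gene of RIG-I signalling (1.64, 1.04 to 2.30), Cacng7 (2.06, 1.02 to 3.34), Exoc3l (2.56, 0.92 to 5.01) and the tight junction gene Ocln (2.42, 0.85 to 4.94). For Slc17a9, Exoc3l and Ocln these rest on 3, 3 and 2 reads in the control siRNA library with TNF. The 6 firmest on the lower side had 4 to 47 reads in each library. They were Fndc7 (-3.71), the meiotic recombination gene Msh5 (-2.57), the chloride channel gene Clcn1 (-2.72), Tle6 (-2.58), Rundc3b (-2.31) and Plxdc1 (-2.30). Fam131b and Clcn1 share sequence, 9.5% of the one and 6.9% of the other, so reads of one may be counted for the other.

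By list, interferon-stimulated genes had a median difference of 0.216, above all 10000 random lists, with no member past the rule. It went with lower levels in medium with Sirt6 siRNA (median -0.227), while with TNF their levels were not higher with Sirt6 siRNA (-0.074). Across genes the difference also fell with GC content (Spearman correlation -0.2), and removal of that trend was not run for it. The chemokines had a median of 0.115 and no member past the rule, but their mean had the opposite sign (-0.015) and did not lie apart. Cholesterol and fatty acid synthesis lay lower (median -0.064), though not by its mean (percentile 19.18). The other 22 lists did not lie apart. Their medians were 0.068 for NF-kB targets, -0.008 for acute phase, -0.017 for MHC class I, 0.048 for Wnt and R-spondin, -0.150 for sirtuins, 0.018 for glycolysis, 0.004 for hypoxia, 0.061 for ribosomal proteins, 0.021 for junctions, 0.009 for proliferation and 0.021 for p53 targets. They were 0.041 for DNA repair, 0.047 for the unfolded protein response, 0.046 for NRF2, 0.025 for extracellular matrix, 0.039 for epithelial, -0.002 for fibroblast, 0.238 for immune cell and 0.118 for endothelial markers, 0.036 for oxidative phosphorylation, 0.027 for immediate early genes and 0.038 for apoptosis. Members of the lists past the rule included Nos2 (1.05), Serping1 (1.44), Sox9 (1.08) and Ocln on the higher side and Car9 (-1.49), Ankrd37 (-1.29) and Rspo1 on the lower side. The ligand gene Wnt6, named after its value was seen, was also past it on the higher side (1.38). For Nos2 the interval was 0.01 to 2.46, barely leaving out 0. In medium Nos2 had 20 reads with control siRNA and 7 with Sirt6 siRNA.

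In simulated libraries with no true difference of responses, 69 to 85 genes passed this rule with counting error alone and 77 to 104 with the fitted spread added. A sizeable part of the 256 is therefore within counting error. Of the 256, 81.6% had under 50 reads per library on average, and 17 were counted with a minimum of 5 RPM. With at least 50 reads per library on average the excess of lower ones was gone, with 23 higher and 24 lower.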

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

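The tests of shared reads, of both explanations for Rspo1 and of Sirt6 silencing as an explanation were chosen after their results were seen, while the tests of GC content, counting error and a single library were not.

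For some named genes, the 2 libraries of one comparison moved one way and the 2 libraries of the matching comparison the other way. None of these differences was tested against replicates. For TNF against medium, the log2 ratio with control siRNA and then with Sirt6 siRNA was -0.99 and 1.52 for Prss16, -1.34 and 0.72 for Cacng7, 1.97 and -1.74 for Fndc7, 1.51 and -1.06 for Msh5, 1.25 and -1.06 for Rundc3b, and 1.25 and -1.05 for Plxdc1. For Sirt6 siRNA against control siRNA, the log2 ratio in medium and then with TNF was 2.02 and -1.69 for Fndc7, 1.36 and -1.22 for Msh5, 1.35 and -1.38 for Clcn1, 1.01 and -1.29 for Plxdc1, and 0.56 and -0.92 for Car9. These genes had 4 to 100 reads in each library. Across all 15274 genes, 5 passed the size rule in opposite directions for TNF, where independent lists would give 9.31, and 5 for silencing, where they would give 0.81. These expected numbers take every gene as equally likely to pass. Calls for silencing gathered among thinly read genes, so 0.81 is too low and no excess can be read from it. Besides those above, the unnamed model Gm16519, named after its values were seen, was the fifth in each.

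Across 8047 well-read genes, the average effect of Sirt6 siRNA ran opposite to the average effect of TNF, with a correlation across genes of -0.27. Of the genes TNF raised under both siRNAs, 73.0% had an average silencing effect below 0, and of those TNF lowered, 68.8% had one above 0. Removing each comparison's trends on GC content and transcript length left the correlation at -0.251, simulated counting error gave -0.037 to 0.043 in 100 simulations, and the correlation was -0.34 for silencing in medium and -0.128 with TNF, so these 3 tests argue against such trends, counting error or a single library as the whole cause. Sirt6 silencing may be the cause, as a hypothesis, but with 1 library per group it cannot be told apart from a difference between wells. Genes are not independent replicates, and the spread between wells was not measured.

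Some genes had exactly the same reads in all 4 libraries. With at least 20 reads in each, there were 62 such groups with 137 genes, where 100 simulated tables of independent counts gave at most 4 groups. In 49 of the 62 groups, 24 of them by name, the members shared a name or a 50-base sequence, so reads counted at every matching gene are a likely cause. No biological explanation was tested.

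Rspo1 was lowest with Sirt6 siRNA and TNF together. Its 95% counting interval had an upper bound of -0.52 in log2, and 3 of 500 genes of like read count had a difference as large. Neither value decides, because the study may have chosen the gene from these libraries; widened for a choice among all 15274 genes, the interval reached 0.45. Counting error, spread between wells and an effect of Sirt6 under TNF therefore all stay open.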

How the results depend on the processing

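Some alternatives were chosen after seeing the data. They left out genes by name or identical reads, required 50 reads per library on average, or removed GC and length trends. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers, apart from the additive model, which compares TNF with medium within each siRNA. Under the alternatives run for them, the Sirt6 log2 ratios (9 each) kept direction. They and the 412 ratios of named genes stayed within their counting intervals. Of the list percentiles rerun, 271 stayed on their side of the 2.5% limits while 24 did not. Only lists apart the same way in both comparisons of TNF or of silencing, or apart for the difference, were rerun. Results of lists apart in 1 comparison alone or within the random range were not rerun. Among named genes the average TNF ratio of Sirt4, near 0 (0.028), turned with total counts (-0.004) and upper-quartile scaling (-0.012), and that of Sirt2 (-0.002) was 0.000 with DESeq2 size factors. The mean difference of the chemokines (-0.015) had the opposite sign to their median, and without a filter acute phase genes lay at percentile 57.12 for silencing in medium. The counts moved with the fold threshold and with the minimum depth. Scaling by DESeq2, upper quartile or total counts kept each within 1.5 times. So did leaving out unnamed Gm models, pseudogenes by name and repeats of genes with identical reads (485, 515, 140, 143, 299, 26 and 202). These were 2396 of the genes compared, left out by name or identical reads and not by measured sharing of sequence. The split for TNF with Sirt6 siRNA was 301 higher and 280 lower with upper-quartile scaling.

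In the order TNF with control siRNA, TNF with Sirt6 siRNA, silencing in medium, silencing with TNF, silencing in both and the difference, a minimum of 5 RPM gave 284, 321, 14, 15, 4 and 17 genes. Rspo1 was not tested there. The split for silencing with TNF was 9 higher and 6 lower, and for silencing in both 2 and 2. A minimum of 50 reads gave 304, 350, 21, 22, 5 and 47, with 12 higher and 10 lower for silencing with TNF and 23 and 24 for the difference. The deposited RPM, with a larger pseudocount (1 RPM) and no counting interval, gave 288, 313, 11, 11, 3 and 30. The share higher among the last was 75.0%, 71.2% and 18.2% for the first 3 and 23.3% for the difference, against 64.9%, 59.4%, 48.4% and 35.5% as reported. A 1.5-fold threshold gave 1435, 1494, 487, 496, 91 and 661, with 793 for TNF under both siRNAs, and 676 higher and 818 lower for TNF with Sirt6 siRNA. A 3-fold threshold gave 185, 207, 20, 40, 1 and 64, with 131 for TNF under both. No filter gave 843 for TNF with Sirt6 siRNA, 402 and 388 for silencing and 451 for the difference. A prior count of 5 gave 98 for silencing in medium. The additive model gave 4506 genes for TNF and 1006 for silencing. It differs in several choices at once, so the cause was not tested. With random lists not matched on expression, 9 of 15 lists stayed apart for TNF in both comparisons; the cause was not tested. With GC and length trends removed, 3 of 4 lists stayed apart for silencing, acute phase genes being at percentile 3.2 in medium.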

Other observations

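The genes and list in the next paragraphs were chosen after their values were seen, and no test here was planned.

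Guanylate-binding protein genes, interferon-induced GTPases of cell-autonomous defence, rose together with TNF. All 12 measured Gbp entries, of which 2 with separate identifiers are named Gbp11, passed the size rule under both siRNAs, with median log2 ratios of 2.43 with control siRNA and 2.56 with Sirt6 siRNA. Sequence shared within the family was not measured for most members, so the entries are not independent counts. Gbp4 went from 15.4 to 93.4 RPM with control siRNA and from 12.1 to 98.0 with Sirt6 siRNA, and Gbp6 from 13.7 to 79.5 and from 12.8 to 80.5. Among 417 families of genes with a common name stem, the next highest medians were those of Cxcl (1.14 and 1.55), Ifi (1.08 and 1.30) and Oas (1.05 and 1.10), with 6 of 11, 5 of 10 and 4 of 6 members past the rule upward in both. By the mean of the 2 medians, the 5 lowest were the Eph receptor stem Ephb (-0.74 and -0.64), the homeobox stems Hoxa (-0.31 and -0.71) and Hoxd (-0.51 and -0.46), Plekhg (-0.35 and -0.58) and the histone stem Hist (-0.37 and -0.54), of which 1 Ephb member and no member of the other 4 fell in both. The order differed within each comparison.

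Of 14 hedgehog pathway genes 11 were measured, of which 2 fell with TNF under control siRNA and 3 under Sirt6 siRNA, and none rose. Their median log2 ratios were -0.409 and -0.448. Gli2, a transcription factor of the pathway, went from 109 to 12 reads and from 140 to 40 (log2 -2.74 and -1.59), and the co-receptor gene Cdon fell in both comparisons. Gas1, another co-receptor gene, had ratios of -0.79 and -1.11, and the signal transducer gene Smo -0.49 and -0.47. For Sirt6 siRNA the medians were 0.080 in medium and 0.101 with TNF, and Gli2 was higher with TNF (1.42).

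Transcripts that mark intestinal epithelium were near the floor. Over the 4 libraries together Epcam had 2 reads, Vil1 4, Cdx2 2 and Krt20 9. In the control siRNA library in medium, Cdh1 was at 13.8 RPM, Krt8 at 656, Krt18 at 612, Upk3b at 1251, Vim at 2073, Col1a1 at 3212 and Fn1 at 4790. The name colonocytes is the labels', and these levels leave open which cell type the line resembled, which was not tested.

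Across 8143 genes with at least 20 RPM on average, the log2 ratios of the 2 TNF comparisons had a correlation across genes of 0.923 and the same sign in 79.4%. For the 2 silencing comparisons these were 0.542 and 64.3%. The ratio of Sirt6 siRNA to control siRNA in medium was higher for genes of higher GC content, with a Spearman correlation across 11619 genes of 0.264, and medians from -0.095 in 626 genes under 40% GC to 0.064 in 425 genes at 60% or more. For the other comparisons it was 0.053 (silencing with TNF), -0.153 (TNF, control siRNA) and -0.275 (TNF, Sirt6 siRNA), and for the difference of the TNF responses it was -0.2.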
